A study of Mus musculus with 15 samples.

How the data were processed

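Ventricles of 15 mice with an inducible Celf1 transgene or without it were profiled by sequencing of polyadenylated RNA. Per the labels the activator was driven by the alpha-myosin heavy chain promoter, the transgene was Flag-tagged human Celf1 behind a tetracycline-responsive promoter, doxycycline was given in food at 2 g per kg, and the atria and a small part of the apex were removed. Food was withdrawn for 2 to 3 hours before the doxycycline food was given. Groups were taken from the labels: control after 72 hours of doxycycline, and induced mice after 12, 24 and 72 hours and 7 days, with 3 mice each. Replicates are the mouse numbers of the labels, and the library number pairs no mice across groups.

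The authors deposited 1 table of values in RPKM, reads per kilobase of gene model scaled to the number of mapped reads, rounded to 2 decimals. Per the submitters' processing notes reads were aligned with TopHat and Bowtie to mm9. Their versions, the counting tool and the strand of the reads are not given in the sources used here. The table has 16042 genes and 20 columns, since 5 mice have 2 columns each, and these were averaged. Each column carries 1 of 9 codes whose meaning is not stated. The 3 controls share 1 code with 1 mouse of the 72 hour group (A3278), and the codes of the 24 hour group occur in no other group. The other times share codes among themselves, except for the code of the 12 hour mouse A3252, which no other mouse has.

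No read counts were given, so depth was estimated from the smallest step between the values of 90 olfactory receptor genes with 1 exon. On simulated columns 60 of 60 estimates lay within 5% of the true depth. The estimates were 16.6 to 52.5 M reads per column. At 1 RPKM a gene model of 1 kilobase holds as many reads as the column has M reads, so counting error is largest for short genes near that limit. Values were transformed to log2(RPKM + 1), and 10868 genes with a mean RPKM of at least 1 over the 15 mice were kept. Counts were not reconstructed, and no count model was used.

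One limma fit (version 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with trend) held all 15 libraries in 5 groups, with 10 residual degrees of freedom and 7.12 prior degrees of freedom. Each time was compared with control, successive times were compared with each other, and an F test covered all groups. P values were adjusted by Benjamini and Hochberg within a comparison, with a threshold of 0.05. Celf1 also had an exact permutation test. Only the 72 hour comparison is matched for time on doxycycline.

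There were 38 gene lists with 788 members, of which 767 were found in the table. They cover splicing, sarcomere, channels, energy supply, the clock, stress and damage responses, protein synthesis and breakdown, the cell cycle, matrix, inflammation and markers of other cell types. Camera tested the 37 lists with at least 2 measured genes at each time with a preset correlation of 0.01, and again with the correlation estimated from the libraries, and fry was run as another test. Every p of a list, also where called camera p, is adjusted by Benjamini and Hochberg over the 37 lists within a time. The lists, comparisons, tests, the rule for gene names and the first set of alternatives were fixed before the data were examined. Among genes past the threshold whose 3 values did not overlap those compared, the rule takes the 10 largest changes in each direction against control and the 5 largest between successive times. It adds Celf1, up to 4 members of each list with the smallest p, and 13 reference genes. A part of the genes that the rule takes is given. Atp2a2, Mki67, Rbm20, Ppargc1a, Isg15 and Hba-a1 were among the list members not analysed here.

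Genes are given by the symbols of the table, some of which have since been replaced, except for newer symbols for Celf1 (Cugbp1), Celf2 (Cugbp2), Cox20 (2310005N03Rik), Eloc (Tceb1), Hmgn5 (Nsbp1), Mpc1 (Brp44l), Hnrnph1 (Hnrph1), Srsf10 (Fusip1), Rbfox1 (A2bp1), Foxo3 (Foxo3a), Fam166a (BC061039), Nmrk2 (Itgb1bp3), Chil3 (Chi3l3) and Bhlhe40 (Bhlhb2). Overlapping exons were looked up in the vM1 annotation of GENCODE, from which GC content and untranslated regions were also taken for genes with a match.

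The first set of alternatives was a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, robust empirical Bayes, a fit of the 2 compared groups alone, the 2 other set tests, and leaving out each library in turn. A GC correction by a lowess curve in each library with a span of 0.3, the use of the first column of each mouse, the column code as a term with the mouse as a random block (16 columns, mouse correlation 0.283, without the 24 hour group), and the columns with the controls' code alone were added after the data had been seen. Outlier tests were left out because groups of 3 are too small. Splicing could not be measured from a table of gene values and was left out.

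The fit was tested on simulated data with 200 of 10868 genes changed between 72 hours and control, in 10 draws. It recovered 13.3% of genes changed 1.5-fold, 70.2% of those changed 2-fold and 99.4% of those changed 4-fold, with 5.29% false calls. A shifted list was called in 10 of 10 draws, and 0 genes were called where nothing had changed. The simulated noise was independent between genes, with no GC trend and no effect of the column code. These rates therefore do not cover errors from such sources in the data. Overlaps between times were set against simulated unchanged groups that share a simulated control group. Each library was the control mean plus residuals, with the residuals of all 15 libraries reassigned at random, also to the controls. The GU-rich element test and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.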

Results

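Ventricle RNA from 15 mice aged 20 to 22 weeks was compared in 5 groups of 3 mice. The control mice carried the heart-specific activator alone and had doxycycline for 72 hours. The other mice also carried the inducible Celf1 transgene and had doxycycline for 12 hours, 24 hours, 72 hours or 7 days. The deposited table holds RPKM for 16042 genes in 20 columns, and 10868 genes with a mean RPKM of at least 1 were tested. Depth estimated from the step between values was 16.6 to 52.5 M reads per column, with a median of 26.8 M. Folds are log2 differences of log2(RPKM + 1) from control, with the standard error, for 3 mice against 3. The standard error is the moderated one from the fit of all 15 libraries, so it is not the spread of the compared mice alone. Unless stated otherwise, the 3 values of a gene given with a fold lay all on 1 side of the 3 values they were compared with. The median of all tested genes stood at -0.30 at 12 hours, -0.19 at 24 hours, -0.10 at 72 hours and -0.03 at 7 days on the deposited scale, so early folds are read against that shift.

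Celf1, an RNA-binding regulator of splicing and messenger RNA decay and the gene induced here, rose by 3.08 ± 0.20 at 12 hours, 3.40 ± 0.20 at 24 hours and 2.29 ± 0.20 at 72 hours. At 7 days its fold was -0.07 ± 0.20, with overlapping groups and an adjusted p of 0.771 in limma. Its RPKM was 33.8, 36.1 and 33.3 in the control hearts, 351, 220 and 345 at 12 hours, 416, 423 and 295 at 24 hours, 179, 181 and 159 at 72 hours, and 29.5, 30.9 and 37.9 at 7 days. Adjusted p was 8.73e-08, 3.54e-08 and 1.79e-06 at the 3 earlier times. The exact permutation p was 0.1 at each of these and 0.5 at 7 days, where 0.1 is the smallest that 3 against 3 can give. The row covers the mouse gene on chromosome 2 from 90780539 to 90859654, and human transgene reads count only as far as they aligned to it.

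**Figure D1:**
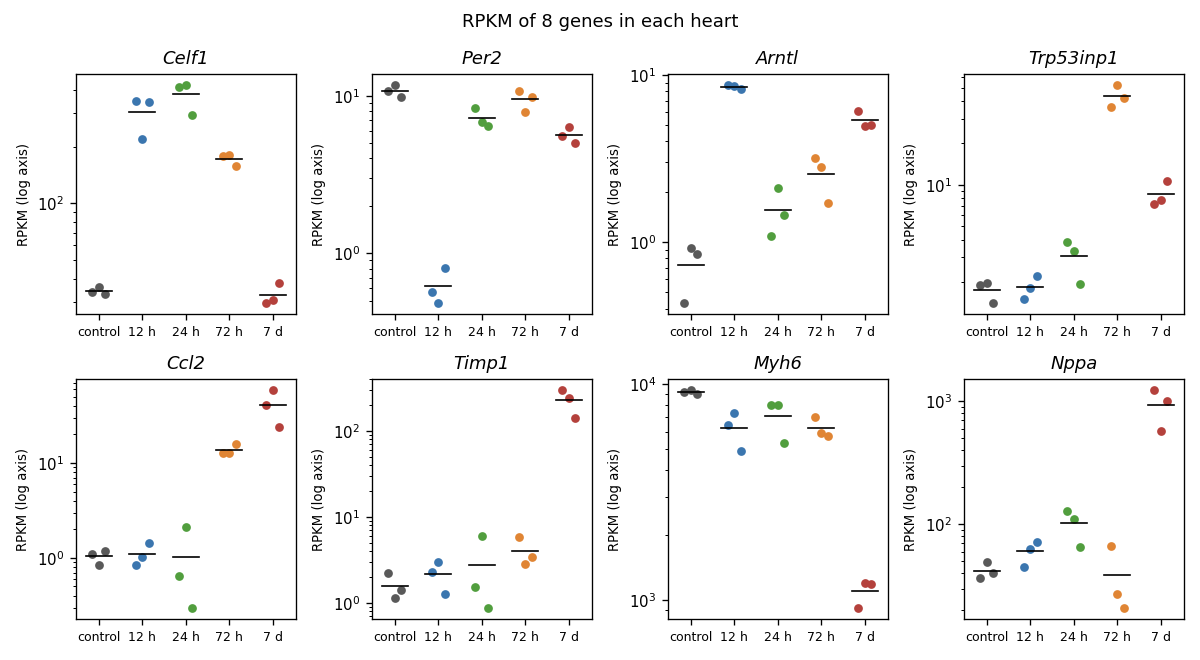
RPKM of 8 genes in each of the 15 hearts, on log axes. Each point is 1 mouse and each line is the mean of 3 mice.

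At 12 hours several genes of the circadian clock were among those that moved. Only this group did not have doxycycline for whole days, and harvest times are not given, so time of day may go with the group here. Per2, a repressor of the clock (-2.86 ± 0.17), Per3 (-2.14 ± 0.19) and the output factors Dbp (-3.43 ± 0.34) and Tef (-2.24 ± 0.21) fell, while the activator Arntl rose by 2.47 ± 0.20. Tfrc, the transferrin receptor, rose by 1.62 ± 0.22, the matrix protein gene Spon2 by 2.07 ± 0.29, the collagen gene Col5a3 by 1.54 ± 0.19 and the embryonic myosin gene Myh3 by 1.73 ± 0.27. Foxo3, an activator of muscle wasting genes (-1.73 ± 0.21), the glucose transporter Slc2a1 (-1.28 ± 0.20) and the RNA-binding protein Rbm24 (-1.39 ± 0.21) fell. So did Cebpb (-2.97 ± 0.53), Mrfap1 (-2.49 ± 0.39) and the chaperone gene Hspa1b (-2.39 ± 0.35). In a fit with the column code, linked to the controls by mouse A3278 alone, Myh3 was at 0.42, Cebpb at -1.07 and Mrfap1 at -0.78. Arntl and Col5a3 were larger there, at 2.77 and 2.06. Dbp shares exon sequence with Sphk2 on the opposite strand and Hspa1b is nearly identical to Hspa1a, and the strand of the reads is not given, so both are uncertain as to source.

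In limma 1432 of 10868 genes passed an adjusted p of 0.05 at 12 hours, 57 higher and 1375 lower. With each library scaled by its median ratio 229 genes passed, 72 higher and 157 lower, and 200 of them had passed in the same direction without it. Most of the lower calls thus go with the shift of the whole library. The counts without 1 library ran from 137, without control mouse A3280, to 1395. Of 35 genes followed at 12 hours, 18 stayed past the test under the alternatives run for them other than the column code, among them Celf1, Arntl, Per2, Per3, Dbp, Tef, Spon2, Col5a3, Tfrc and Foxo3. With the column code as a term, where the link to the controls is mouse A3278 of the 72 hour group alone, 9 genes passed, and Celf1, Arntl, Per2, Tef and Col5a3 were among them. The 3 induced values lay all on 1 side of the controls in 47.6% of genes, 500 above and 4677 below. For a single unchanged gene the chance is 10%. A shift of a whole library moves many genes together, so 10% is no benchmark for a share of genes.

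Of 18 clock genes 11 fell and 1 rose at 12 hours, with a median of -1.07 (adjusted over the list alone 13 and 3). The list passed camera at an adjusted p of 0.0013, and had an adjusted p of 0.872 with an estimated correlation. All list p values given, including each camera p, are adjusted over the lists within a time. Of 20 cardiac transcription factor genes 9 fell (16 adjusted over the list alone), such as Gata6 at -1.18 ± 0.24, Tbx5 at -0.80 ± 0.18 and Nkx2-5 at -1.82 ± 0.42. The falls of Tbx5 and Nkx2-5 did not pass with either other scaling, and that of Gata6 did not pass without control mouse A3259 or A3280. With the column code as a term Nkx2-5 changed sign, at 0.039. The list's adjusted camera p was 0.00151, and 0.872 with an estimated correlation. Of 24 immediate early genes 7 fell (12 adjusted over the list alone), among them Jun at -1.37 ± 0.29 and Nr4a3 at -0.92 ± 0.19, with a camera p of 0.0399 and an adjusted p of 0.872 with an estimated correlation. Neither fall passed without control mouse A3259, and the list did not pass in 3 other settings.

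Camera called 4 lists higher at 12 hours, oxidative phosphorylation, cytosolic ribosomal proteins, macrophage markers and neutrophil markers, at 0.00258, 0.0219, 0.0128 and 0.00151. All had an adjusted p of 0.872 with an estimated correlation. The medians were -0.13, -0.17, 0.03 and 0.69 and the means -0.07, -0.13, -0.02 and 0.63, so in the first 3 the test differs in sign from the median or the mean. Over all 37 lists such a difference occurred in 18 at 12 hours, 11 at 24 hours, 7 at 72 hours and 1 at 7 days. Of 53 oxidative phosphorylation genes 3 rose and 1 fell (1 and 0 adjusted over the list alone), with Uqcrb at 1.41 ± 0.34. Of 61 ribosomal protein genes Rps27 alone rose (0 adjusted over the list alone), by 0.83 ± 0.22. Of 21 macrophage genes 0 passed, and of 4 neutrophil genes S100a9 rose by 1.16 ± 0.35 with overlapping groups, the same counts as adjusted over the list alone. These 4 lists also did not pass in 3, 5, 6 and 3 other settings. Uqcrb and Rps27 did not pass without control mouse A3259 or A3280, and S100a9 passed neither without any of the 3 controls nor with another scaling.

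At 24 hours Eif5, a translation initiation factor, rose by 1.95 ± 0.25, the elongin subunit Eloc by 1.99 ± 0.29, the chromatin protein Hmgn5 by 1.98 ± 0.32 and the assembly factor Cox20 by 2.24 ± 0.37. Trim63, a muscle ubiquitin ligase, rose by 1.12 ± 0.19. The chemokine Cxcl12 (-2.32 ± 0.35), the flow-sensitive factor Klf2 (-2.17 ± 0.38), the mitochondrial pyruvate carrier Mpc1 (-2.00 ± 0.25), phospholamban, or Pln (-1.36 ± 0.23), and Rbm24 (-1.44 ± 0.21) fell. Each of these 10 genes stayed past the test under all the alternatives run for it.

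Of 20 cardiac transcription factor genes 7 fell at 24 hours (13 adjusted over the list alone), with Tbx5 at -1.17 ± 0.18 and Hand2 at -1.39 ± 0.37. This was the 1 list past camera, at 0.0288, and its adjusted p was 0.921 with an estimated correlation. It also did not pass in 3 other settings, where its p reached 0.111. The fall of Hand2 did not pass after GC correction, nor without control mouse A3259 or A3280 or mouse A3262. Of 21 endoplasmic reticulum stress genes 4 rose (4 adjusted over the list alone), such as Pdia3 at 0.79 ± 0.17 and Hsp90b1 at 0.69 ± 0.20, and 17 did not pass, with an adjusted camera p of 0.137. Of 23 splicing regulator genes 3 rose and 5 fell (3 and 7 adjusted over the list alone), with Hnrnph1 at 0.78 ± 0.17, Srsf10 at 0.91 ± 0.21 and a camera p of 0.938. Pdia3, Hsp90b1, Hnrnph1 and Srsf10 did not pass without mouse A3262 or control mouse A3280. Nppa, the atrial natriuretic peptide gene, rose by 1.21 ± 0.37, a call lost when any 1 of the 6 mice was left out.

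In limma 1736 genes passed at 24 hours, 585 higher and 1151 lower. Median scaling gave 1670, 916 higher and 754 lower, so the share of higher calls depends on the scale. The counts without 1 library ran from 39, without control mouse A3280, to 1841, and were 139 without mouse A3262 and 216 without control mouse A3259. The column codes of the 24 hour libraries occur in no other group, so code and group cannot be told apart there. The induced values lay on 1 side of the controls in 46.8% of genes, 1508 above and 3577 below, where 10% is the chance for a single gene only.

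The lower calls at both early times lie among GC-rich genes. Of the 1375 genes lower at 12 hours 840 were in the tertile of genes with the highest GC content and 105 in the lowest tertile. Of the 1151 genes lower at 24 hours 671 and 96 were in these tertiles. Of the 585 genes higher at 24 hours 497 were in the lowest tertile and 12 in the highest. Across 10582 genes with a known GC content, the Spearman correlation of fold with GC content was -0.57 at 12 hours, -0.58 at 24 hours, -0.36 at 72 hours and -0.37 at 7 days. Single columns against the control mean reached -0.52 and 0.51 among the controls themselves. These were taken only over the 7295 genes with a mean RPKM of at least 5. With each library corrected for GC content 185 genes passed at 12 hours and 1043 at 24 hours. Of these, 139 and 664 had passed in the same direction without the correction.

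**Figure D2:**
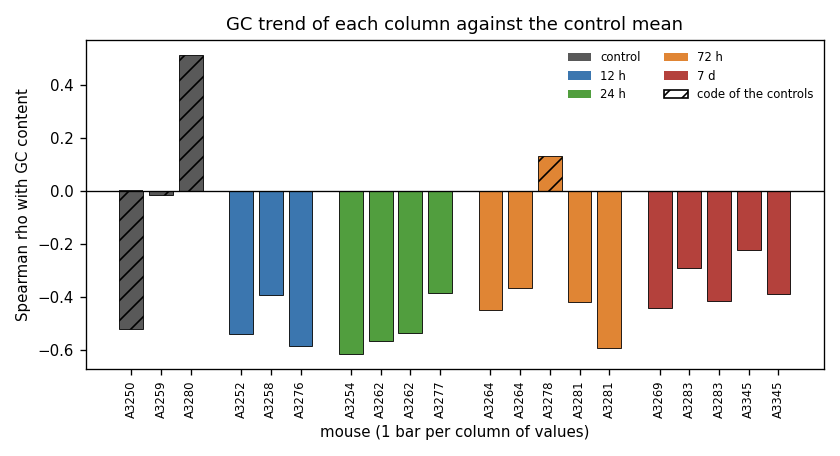
Spearman correlation of each column's difference from the control mean with GC content, over genes with a mean RPKM of at least 5. Hatched bars share the column code of the controls.

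At 72 hours targets of the tumour suppressor p53 rose. Trp53inp1 rose by 4.01 ± 0.21, the receptor Eda2r by 3.24 ± 0.24, the cell cycle inhibitor Cdkn1a by 2.68 ± 0.30 and the p53 ligase Mdm2 by 2.33 ± 0.19. The largest rises were those of 1700007K13Rik, at 5.58 ± 0.27, and Gtse1, a regulator of p53 in dividing cells, at 4.46 ± 0.34. The stress hormone Gdf15 rose by 2.55 ± 0.35, the stress sensor Sesn2 by 1.95 ± 0.22 and Ddit4l, an inhibitor of growth signalling, by 2.64 ± 0.34. The reductase Dcxr rose by 2.91 ± 0.21 and the haem oxygenase Hmox1 by 2.27 ± 0.31, while the quinone reductase Nqo1 fell by 1.17 ± 0.20. Fam166a rose by 4.22 ± 0.33, but shares exon sequence with Tubb2c on the opposite strand. The adjusted p of these genes ran from 1.49e-09 to 0.00161.

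Of 17 p53 and apoptosis genes 11 rose at 72 hours and 0 fell (12 adjusted over the list alone), with a median of 0.98. The list passed camera at 9.65e-13 and had an adjusted p of 0.00169 with an estimated correlation, the 1 list of 37 to pass with it at any time. Of 13 acute inflammation genes 9 rose (10 adjusted over the list alone), such as the chemokines Ccl2 at 2.85 ± 0.30 and Ccl7 at 2.67 ± 0.46, Saa3 at 2.23 ± 0.33 and Sele at 1.33 ± 0.25. Its camera p was 3.83e-09, with an adjusted p of 0.222 with an estimated correlation. Of 24 immediate early genes 10 rose (10 adjusted over the list alone), such as Atf3 at 2.11 ± 0.30, Btg2 at 2.06 ± 0.28 and Fos at 1.82 ± 0.34, with 8.41e-07 in camera and an adjusted p of 0.518 with an estimated correlation, and did not pass with fry, at 0.0822. Of 30 proteasome genes 10 rose (13 adjusted over the list alone), such as Psma5 at 1.18 ± 0.21 and Psmd7 at 1.03 ± 0.20, with 1.22e-06 and an adjusted p of 0.518 with an estimated correlation. Of 21 endoplasmic reticulum stress genes 5 rose and 1 fell (7 and 2 adjusted over the list alone), with Pdia3 at 1.46 ± 0.17, a camera p of 0.00167 and an adjusted p of 0.518 with an estimated correlation. Of 22 cell cycle genes 3 rose (3 adjusted over the list alone), among them Rrm2 at 1.63 ± 0.26, with a camera p of 0.0273 and an adjusted p of 0.814 with an estimated correlation. This list also did not pass in 7 other settings, among them both scalings, the GC correction, fry, and without mouse A3259 or A3278, over which its p reached 0.434.

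Several lists of heart muscle genes were lower at 72 hours, though most of their members did not pass. Of 22 ion channel and connexin genes 10 fell (15 adjusted over the list alone), such as the potassium channel genes Kcnj3 at -0.82 ± 0.15 and Kcnj11 at -1.04 ± 0.24. The list passed camera at 8.41e-07 and had an adjusted p of 0.369 with an estimated correlation. Of 23 sarcomere genes 7 fell (14 adjusted over the list alone), with Myom1 at -0.62 ± 0.17 and 1.38e-05 in camera, against an adjusted p of 0.518 with an estimated correlation. Of 22 fatty acid oxidation genes 4 fell (10 adjusted over the list alone), with Acsl1 at -0.73 ± 0.16 and 0.000163, and an adjusted p of 0.518 with an estimated correlation. Of 53 oxidative phosphorylation genes 4 fell (4 adjusted over the list alone), with Atp5g3 at -0.99 ± 0.19 and 0.00178, and an adjusted p of 0.726 with an estimated correlation. With quantile normalization the sarcomere and oxidative phosphorylation lists did not pass, at 0.132 and 0.622, nor did oxidative phosphorylation with fry. Of 16 calcium handling genes 3 fell (5 adjusted over the list alone), with an adjusted camera p of 0.0549. Kcnj11 did not pass in 2 of the alternatives, and Myom1 in 6.

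A further 6 lists were lower at 72 hours. Cardiac transcription factors had 3 of 20 lower (7 adjusted over the list alone), such as Tbx5 at -0.83 ± 0.18, and genes with known splicing changes in myotonic dystrophy 6 of 20 (11 lower and 1 higher adjusted over the list alone), such as Pdlim5 at -0.83 ± 0.23. The camera p was 0.000139 and 0.00178, with an adjusted p of 0.518 with an estimated correlation for both. Glycolysis had 4 of 19 lower (8 adjusted over the list alone), such as Hk2 at -0.73 ± 0.17, the citric acid cycle list 1 of 18 (5 adjusted over the list alone), Idh3a at -0.66 ± 0.16, and the fasting list 2 of 14 (6 lower and 1 higher adjusted over the list alone), such as Mlycd at -0.82 ± 0.19. The camera p was 0.000563, 0.0392 and 0.0377, with an adjusted p of 0.714 with an estimated correlation for each. The citric acid cycle and fasting lists also did not pass in 5 other settings each, nor glycolysis with fry. Tbx5, Hk2, Mlycd and Pdlim5 did not pass without control mouse A3280, nor Idh3a without control mouse A3250. Of 6 atrial marker genes 3 fell (4 adjusted over the list alone), with a camera p of 0.0173 and an adjusted p of 0.518 with an estimated correlation. Myl7 among them, at -1.62 ± 0.48 with overlapping groups, was at 0.14 in mouse A3278, so its fall rests on A3281 and A3264.

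In limma 1262 genes passed at 72 hours, 695 higher and 567 lower, and 1503 after median scaling, 882 higher and 621 lower. Of the calls over 2-fold 308 were higher and 50 lower. The counts without 1 library ran from 468, without mouse A3281, to 2481, without mouse A3278, of which 982 were higher and 1499 lower, so most calls are then lower. Mouse A3278 shares its column code with the 3 controls and no other mouse does. In A3278 alone against the controls, with the spread taken from the other groups, 268 genes passed, 235 higher. With the code as a term 376 passed, 322 higher, but only A3278 links the controls to the other codes, so the folds in that fit are again those of 1 mouse and give no second check. Of 58 genes followed at 72 hours 36 stayed past the test under the alternatives run for them other than those on the column code, among them Trp53inp1, Eda2r, Cdkn1a, Mdm2, Ccl2 and Ccl7. In the fit with the code 31 of the 58 passed. The induced values lay on 1 side of the controls in 35.0% of genes, 1687 above and 2122 below, where 10% is the chance for a single gene only. This is the comparison in which both groups had doxycycline for 72 hours.

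By 7 days genes of the matrix and of macrophages rose, and many genes of contraction and energy supply fell. None of the lists behind this passed with an estimated correlation. Whether the falls lie within muscle cells or in the share of muscle RNA in the ventricle was not tested. Timp1, an inhibitor of matrix proteases, rose by 6.44 ± 0.39, osteopontin (Spp1) by 6.30 ± 0.27 and the collagen cross-linker Lox by 5.98 ± 0.22. The macrophage genes Lgals3 and Ccl6 rose by 5.71 ± 0.28 and 5.90 ± 0.31, and Arg1 by 5.10 ± 0.36. The main myosin gene of the adult ventricle, Myh6 (-3.07 ± 0.21), and Myh7 (-2.85 ± 0.20) fell, though the pair share near-identical sequence. Titin-cap, or Tcap (-4.28 ± 0.27), the ribosomal variant Rpl3l of mature muscle (-4.32 ± 0.21), the potassium channel subunit Kcnip2 (-3.58 ± 0.19) and the splicing regulator Rbfox1 (-3.27 ± 0.26) fell too. Nppa rose by 4.39 ± 0.37 and Nppb by 2.36 ± 0.35, both hormones of the strained heart, and Celf2 rose by 0.80 ± 0.22, a call lost after GC correction and with the column code as a term. The adjusted p of these genes ran from 7.22e-12 to 0.00562.

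Of 32 extracellular matrix genes 31 rose (31 adjusted over the list alone), with a median of 2.85, and Col5a2 was at 4.18 ± 0.21. Of 21 macrophage genes 21 rose (21 adjusted over the list alone), with a median of 2.77 and Mrc1 at 4.15 ± 0.17. The camera p was 1.54e-18 and 3.28e-15, and each list had an adjusted p of 0.211 with an estimated correlation. Of 53 oxidative phosphorylation genes 50 fell and 1 rose, of 18 citric acid cycle genes 18 fell and of 22 fatty acid oxidation genes 21 fell and 1 rose, the same counts as adjusted over the list alone. The medians were -1.55, -1.56 and -1.57, and examples are Cyc1 at -2.12 ± 0.20, Idh2 at -2.73 ± 0.21 and Cpt2 at -2.47 ± 0.17. The camera p was 1.91e-15, 7.87e-10 and 2.12e-10, and all had an adjusted p of 0.211 with an estimated correlation. Of 13 acute inflammation genes 11 rose (13 adjusted over the list alone), such as Serpina3n at 5.38 ± 0.33, with 5.22e-07 in camera and an adjusted p of 0.211 with an estimated correlation.

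Of 23 sarcomere genes 17 fell and 1 rose at 7 days (19 and 2 adjusted over the list alone), with a median of -1.03, 4.31e-07 in camera and an adjusted p of 0.308 with an estimated correlation. Of 22 ion channel genes 17 fell and 1 rose (17 and 1 adjusted over the list alone), with Abcc9 at -1.79 ± 0.18, 7.97e-06 and an adjusted p of 0.257 with an estimated correlation. The calcium release channel gene Ryr2 was at 0.37 ± 0.22, with an adjusted p of 0.167. Of 20 cardiac transcription factors 14 fell (14 adjusted over the list alone), with Esrrb at -1.76 ± 0.18, 0.000452 and an adjusted p of 0.387 with an estimated correlation. Of 22 cell cycle genes 19 rose (19 adjusted over the list alone), with Ccnb1 at 1.71 ± 0.22, 2.98e-05 and an adjusted p of 0.387 with an estimated correlation, and this list did not pass among genes with a mean RPKM of at least 5, at 0.208. Of 18 heat shock genes 12 fell (12 adjusted over the list alone), with Fkbp4 at -3.00 ± 0.22, 0.00409 and an adjusted p of 0.280 with an estimated correlation.

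**Figure D3:**
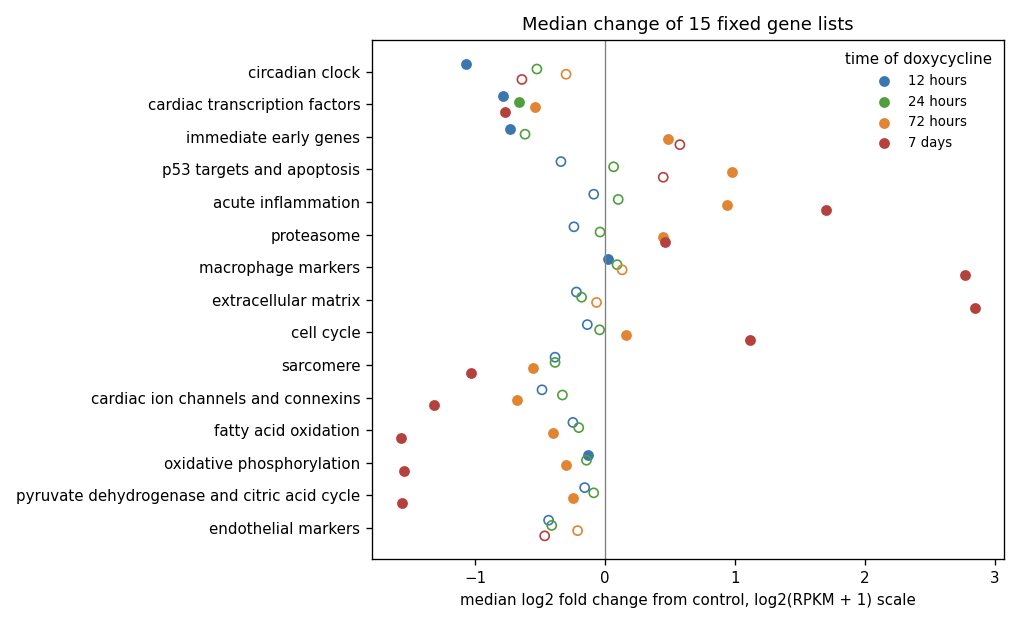
Median log2 fold change of 15 fixed gene lists at each time. Filled points passed camera with the preset correlation of 0.01, and only the p53 list at 72 hours also passed with an estimated correlation.

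Of 21 endoplasmic reticulum stress genes 14 rose and 1 fell at 7 days (14 and 1 adjusted over the list alone), with Edem1 at 2.11 ± 0.15, 0.00864 in camera and an adjusted p of 0.325 with an estimated correlation. Of 30 proteasome genes 15 rose (15 adjusted over the list alone), with Psmd14 at 1.57 ± 0.25, 0.0209 and an adjusted p of 0.703 with an estimated correlation. Of 61 ribosomal protein genes 14 rose (10 adjusted over the list alone), with Rpl3 at 1.60 ± 0.20, 0.0138 and an adjusted p of 0.714 with an estimated correlation. Of 19 glycolysis genes 10 fell and 4 rose (10 and 5 adjusted over the list alone), with Eno3 at -2.74 ± 0.20, 0.0366 and an adjusted p of 0.703 with an estimated correlation. Of 4 neutrophil genes 4 rose (4 adjusted over the list alone), with S100a8 at 3.06 ± 0.35, 0.00463 and an adjusted p of 0.260 with an estimated correlation. Of 4 red blood cell genes 4 fell (4 adjusted over the list alone), with Hbb-b1 at -3.06 ± 0.53, 0.0209 and an adjusted p of 0.325 with an estimated correlation. The glycolysis list also did not pass in 4 other settings, where its p reached 0.351, the ribosomal list in 2, at up to 0.132, and the proteasome and red blood cell lists in 1 each, at 0.0637 and 0.0834. With the column code as a term Psmd14 was at 0.62, S100a8 at 2.73 and Hbb-b1 at -1.59, and none of these passed, at an adjusted p of 0.152, 0.0749 and 0.156. Globin genes share reads with their paralogs.

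The remaining lists did not pass camera at 7 days after adjustment over the lists. Among lists of other cell types, fibroblast markers had 4 of 12 higher and 2 lower, such as Pdgfra at 1.79 ± 0.20, endothelial markers 8 of 19 lower and 0 higher, such as Kdr at -0.84 ± 0.17, which did not pass with the column code as a term, and mural cell markers 6 of 12 higher and 4 lower. Their camera p was 0.337, 0.0828 and 0.741. Atrial markers had 1 of 6 higher and 3 lower, adipocyte markers 1 of 3 lower, epicardial markers 1 of 2 higher, skeletal muscle markers 4 of 11 lower, and nerve markers 0 of 2 past the test, with camera p 0.337, 0.399, 0.646, 0.0691 and 0.907. The 1 lymphocyte gene measured, Cd3e, rose by 3.18 ± 0.27. Splicing regulators had 8 of 23 higher and 4 lower with a camera p of 0.476, a median of 0.22 and a mean of -0.04, which differ in sign. Myotonic dystrophy splicing genes had 3 of 20 higher and 8 lower, fetal stress genes 8 of 13 higher and 2 lower, calcium handling genes 4 of 16 higher and 8 lower, and clock genes 4 of 18 higher and 9 lower, with 0.176, 0.122, 0.337 and 0.157. Fasting genes had 6 of 14 higher and 7 lower, immediate early genes 9 of 24 higher and 2 lower, and interferon genes 1 of 19 higher and 3 lower, with 0.907, 0.0562 and 0.387. The ATF4 list had 9 of 20 higher and 3 lower, NRF2 targets 7 of 16 higher and 4 lower, p53 targets 8 of 17 higher and 3 lower, and atrophy genes 4 of 15 higher and 6 lower, with 0.0998, 0.168, 0.0823 and 0.820. Adjusted over the list alone these counts were the same, except for 7 fasting genes higher, 5 atrophy genes higher, and 0 interferon genes higher and 2 lower.

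In limma 5960 of 10868 genes passed at 7 days, 2899 higher and 3061 lower, and the counts without 1 library ran from 4956 to 5513. Median scaling gave 6230 genes. Of 74 called genes followed at 7 days 73 stayed past the test under the alternatives run for them other than the column code. With the column code as a term, linked to the controls by mouse A3278 alone, 3171 passed, 2102 higher and 1069 lower, among them 66 of these 74 genes. The induced values lay on 1 side of the controls in 66.9% of genes, 3516 above and 3751 below, where 10% is the chance for a single gene only. The F test over the 5 groups called 7746 genes.

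Between 12 and 24 hours 426 genes differed in limma, 364 higher and 62 lower at 24 hours, and 203 and 252 after median scaling. The count was 134 with only these groups in the fit, 731 after GC correction and 95 without mouse A3277. Dbp rose by 2.43 ± 0.34, Per2 by 2.34 ± 0.17 and the glucocorticoid target Zbtb16 by 1.98 ± 0.15, while Arntl fell by 1.92 ± 0.20. The clock genes among these may also differ by time of day, since 12 hours is not a whole day. Celf1 was 0.32 ± 0.20 higher, with overlapping groups and an adjusted p of 0.367. Between 24 and 72 hours 1113 genes differed, 834 higher and 279 lower, and 881 and 581 after median scaling. The count was 270 with only these groups in the fit, 1908 after GC correction and 474 without mouse A3262. Trp53inp1 rose by 3.48 ± 0.21 and Celf1 fell by 1.11 ± 0.20 (adjusted p 0.0021). Between 72 hours and 7 days 4879 genes differed, 2452 higher and 2427 lower. Celf1 (-2.37 ± 0.20), Myh6 (-2.51 ± 0.21) and Myh7 (-2.41 ± 0.20) fell, while Celf2 rose by 1.08 ± 0.22.

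The 12 and 24 hour comparisons shared 32 higher and 440 lower genes, against 3.07 and 146 for independent lists. The genes shared in the same direction numbered 101 with median scaling, 85 with quantile normalization, 53 after GC correction and 4 without control mouse A3280. The 72 hour and 7 day comparisons shared 433 higher and 466 lower genes, against 185 and 160. Those shared numbered 509 with the first column of each mouse, 326 without control mouse A3280 and 192 with the column code as a term. All comparisons use the same 3 controls, which cannot be split, so part of each overlap may come from the shared controls. Unchanged groups were simulated against a simulated control group that they share, with the residuals of all 15 libraries reassigned at random. The deviations of the real controls are therefore not held fixed. These simulated groups shared 0 genes on average at 12 and 24 hours. Unchanged groups have few calls to share, so this count cannot tell how much of the overlap comes from the shared controls. Their covariance of folds at 12 and 24 hours was 0.0273, against 0.128 in the data. For 72 hours and 7 days the simulated covariance was 0.0283, against 0.25. The correlation of folds was 0.659 at 12 and 24 hours, against a simulated mean of 0.414 and a highest value of 0.845. At 72 hours and 7 days it was 0.501, against 0.480 and 0.909. The share of genes with the same sign was 77.2% and 69.1%, against 63.9% and 67.1% in the simulated groups. Of the other pairs of times, 12 and 72 hours had a correlation of 0.416, 12 hours and 7 days 0.416 and 24 hours and 7 days 0.435, all lower than the simulated means of 0.465, 0.463 and 0.452. For 24 and 72 hours it was 0.537, against 0.426 and a highest value of 0.872. Genes called in opposite directions numbered 3 at 12 and 24 hours, 35 at 72 hours and 7 days, and 18, 120, 97 and 12 in the other pairs in the order given.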

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

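The tests of time of day, of a lasting effect of the Celf1 level, of GC bias between libraries, of the column code, of the Celf1 level behind the GC trend, of mislabelled mice and of the Myh6 promoter, and the counts over other splits of the mice, were chosen only after the result was seen.

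The difference between successive times was itself tested by limma, and each result here passed that test. From 12 to 24 hours 426 genes differed, with Dbp at 2.43, Per2 at 2.34, Zbtb16 at 1.98, Spon2 at -2.27, Myh3 at -1.97, Arntl at -1.92 and Col5a3 at -1.80. From 24 to 72 hours 1113 genes differed, with 1700007K13Rik at 5.40, Gtse1 at 4.72, Trp53inp1 at 3.48, Dcxr at 3.30, Rhox8 at -1.74, Atp5k at -1.64, Nppa at -1.50 with overlapping groups, Celf1 at -1.11, Ryr2 at -0.99 and Actb at 0.97. From 72 hours to 7 days 4879 genes differed. The largest rises were Spp1 at 6.02, Lox at 5.70 and Chil3 at 5.69, and the largest falls Lrtm1 at -3.98, Rpl3l at -3.52 and Dhrs7c at -3.48. Celf1 was at -2.37, Myh6 at -2.51, Myh7 at -2.41, Nppa at 4.69, Nppb at 1.34, Actb at 1.15, Celf2 at 1.08, Ryr2 at 0.79 and Mbnl1 at 0.68. Rhox8, Atp5k, Ryr2 and Actb did not pass from 24 to 72 hours without mouse A3262, nor Nppa without mouse A3264.

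Clock genes changed at 12 hours, and less at 24 and 72 hours. Of the 12 clock genes called at 12 hours 9 had lost the greater part of that change by 24 hours, 12 by 72 hours and only 4 by 7 days, and their median change, signed as at 12 hours, went from 1.85 to 0.58, then 0.45 at 72 hours and 1.19 at 7 days. The 12 were picked by their change at 12 hours, so part of the loss may follow from that choice. Between 12 and 24 hours 8 of them were called. Celf1 RNA stood as high at 24 as at 12 hours, which argues against a lasting effect of its level, though the 24 hour column codes occur in no other group. After the GC correction 11 of the 12 stayed called, all but Bhlhe40, which argues against GC content. The controls and the later times had doxycycline for whole days, and only the 12 hour group did not. A different time of day of harvest may thus explain the pattern at 12 hours, but the hours of start and harvest are not given. Dbp, Hlf and Arntl stood far from control again at 7 days. An effect of Celf1 that passes within a day was not tested, and with the column code as a term in a fit linked to the controls by A3278 alone, all 12 kept their direction but 3 were called.

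GC-rich genes were lower at 12 and 24 hours. Single columns were correlated with GC content only over genes with a mean RPKM of at least 5. Between 2 columns of the same mouse the median absolute Spearman correlation of the difference with GC content was 0.417, so such trends also arise with no difference in mouse. A GC bias between libraries may therefore explain the pattern. The column code cannot be told apart from the group, since the controls share theirs with A3278 alone, and 9 genes were called at 12 hours with the code as a term, a fit that rests on that mouse. An effect of the Celf1 level cannot be told apart either: the 7 day columns, with Celf1 at the control level, had a median correlation of -0.39, but control columns themselves went down to -0.52.

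Celf1 was at the control level at 7 days. The highest correlation of a 7 day library with a control library was 0.844, against at least 0.985 among controls, which argues against mislabelled control mice. Dilution by RNA of other cells would lower all muscle transcripts alike, but the sarcomere genes had a median of -0.90 and a lower quartile of -1.94 from 72 hours to 7 days, against -2.37 for Celf1. The Myh6 promoter drives the activator of the transgene, and Myh6 itself was at -2.51 over this step. Lower activity of the promoter may therefore explain part of the fall. The Celf1 row also covers the mouse gene, at 33.3 to 36.1 RPKM in the controls, so the folds of Celf1 and Myh6 cannot be matched in size. Whether lower promoter activity could bring Celf1 fully back to the control level was not tested. It also leaves open the fall of Celf1 by 1.11 from 24 to 72 hours, when Myh6 was at -0.17 and not called.

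For the comparisons of 3 mice with 3 there are 10 splits, too few for a share under 0.05. In each the real split was 1 of 10 with as many genes: 1432, 1736, 1262 and 5960 against control, and 426 and 4879 between times, with a highest other count of 0, and 1113 from 24 to 72 hours, with a highest other count of 18. For the F test 1 of 100 splits, the real one, gave as many as 7746 genes, and the highest other gave 3315. The F test count argues against a random split of the mice into 5 groups as its source. The 10 splits of each comparison of 3 with 3 cannot decide this. In a split that mixes the groups a real difference also adds to the spread, which lowers the other counts. Neither kind of split can tell the groups from the column codes, which partly go with them.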

How the results depend on the processing

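The GC content correction, the first column of each mouse alone, the column code as a term and the columns with the controls' code alone were tests chosen only after the data were seen. Celf1 kept its call at 12, 24 and 72 hours under every setting run there, and of the genes followed 18 of 35, 12 of 36, 36 of 58 and 73 of 74 called kept theirs at 12 hours, 24 hours, 72 hours and 7 days under the settings run for them, other than those on the code; a gene is not run where a filter drops it or it has no known GC content. The counts at 7 days and from 72 hours to 7 days kept within 1.5 times under all settings but the code at 7 days. The p53 list at 72 hours passed with a pseudocount of 0.1, both filters, both scalings, the GC correction, the estimated correlation, fry and each library left out; lists were not run under the other settings. Except where the construction shows it, as with fewer mice or groups, the cause of a change was not tested. A pseudocount of 0.1 and robust empirical Bayes kept every count of genes within 1.5 times, and 237 of 240 and 238 of 240 gene results. Depth limits short genes near 1 RPKM, and the simulation recovered 13.3% of changes of 1.5-fold.

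With no filter 879 genes were called at 12 hours and 1056 at 24 hours, the 2 times shared 241, the ribosomal list at 12 hours was at 0.157, and 5 lists passed at 24 hours. With a pseudocount of 0.1 this last count was 2. With a mean RPKM of at least 5 it was 0, with cardiac transcription factors at 0.111, and lists lost were macrophage markers at 12 hours (0.144), citric acid cycle (0.0619) and cell cycle (0.334) at 72 hours, and glycolysis (0.101), cell cycle (0.208) and red blood cell markers (0.0834) at 7 days.

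With median-of-ratios scaling 229 genes were called at 12 hours, 101 were shared with 24 hours, and 2 lists passed at 24 hours. The lists lost were macrophage (0.0971) and neutrophil markers (0.152) at 12 hours and citric acid cycle (0.0571) and cell cycle (0.0598) at 72 hours. With quantile normalization 194 genes were called at 12 hours and 85 shared with 24 hours, 3 lists passed at 12 hours and 2 at 24 hours, and Celf1 at 7 days changed sign to 0.0013, uncalled in both. The lists lost were at 12 hours oxidative phosphorylation (0.199), ribosomal proteins (0.524) and macrophage and neutrophil markers (both 0.115), at 72 hours sarcomere (0.132), oxidative phosphorylation (0.622), citric acid cycle (0.780), fasting (0.0700) and cell cycle (0.103), and at 7 days glycolysis (0.351).

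After the GC content correction 185 genes were called at 12 hours and 1043 at 24 hours, with 53 shared, 731 from 12 to 24 hours and 1908 from 24 to 72 hours. Then 11 lists passed at 12 hours and 2 at 24 hours, while fasting (0.0575) and cell cycle (0.0630) at 72 hours and glycolysis at 7 days (0.0643) were lost. With the first column alone 719 genes were called at 12 hours, 729 at 72 hours and 229 from 12 to 24 hours, with 241 shared by 12 and 24 hours and 509 by 72 hours and 7 days. With only the 2 groups compared 3244 genes were called at 12 hours, 134 from 12 to 24 hours and 270 from 24 to 72 hours, and 12 and 24 hours shared 1087. With the column code as a term A3278 alone links the controls to other codes, so each comparison with control rests on that mouse, and 9 genes were called at 12 hours, 376 at 72 hours and 3171 at 7 days, with 192 shared by the last 2. Changed signs were Nkx2-5 at 12 hours (0.039), Myl7 at 72 hours (0.14) and Ryr2 at 7 days (-0.060). The 24 hour group could not be fitted with the code. In the columns with the controls' code 268 genes were called at 72 hours, and Myl7 was again at 0.14.

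With an estimated correlation 0, 0, 1 and 0 lists passed at the 4 times. At 12 hours the 7 lists called by camera all had 0.872 and at 24 hours cardiac transcription factors had 0.921. At 72 hours splicing genes of myotonic dystrophy, sarcomere, cardiac transcription factors, fatty acid oxidation, immediate early genes, endoplasmic reticulum stress, proteasome and atrial markers had 0.518, ion channels 0.369, oxidative phosphorylation 0.726, citric acid cycle, glycolysis and fasting 0.714, inflammation 0.222 and cell cycle 0.814. At 7 days fatty acid oxidation, oxidative phosphorylation, citric acid cycle, matrix, inflammation and macrophage markers had 0.211, sarcomere 0.308, ion channels 0.257, cardiac transcription factors and cell cycle 0.387, glycolysis and proteasome 0.703, endoplasmic reticulum stress and red blood cell markers 0.325, heat shock 0.280, ribosomal proteins 0.714 and neutrophil markers 0.260. With fry 13 lists passed at 12 hours, 0 at 24 hours and 26 at 7 days. At 12 hours it gave the opposite direction for oxidative phosphorylation (0.690), ribosomal proteins (0.624) and macrophage markers (0.942), and lost immediate early genes (0.0820) and neutrophil markers (0.132). It also lost cardiac transcription factors at 24 hours (0.0585), at 72 hours oxidative phosphorylation and fasting (both 0.10), glycolysis (0.0577), immediate early genes (0.0822) and cell cycle (0.434), and ribosomal proteins at 7 days (0.132). Fry asks whether a list moves at all and camera whether it moves more than other genes.

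Leaving out 1 mouse at a time gave 137 to 1395 genes at 12 hours, 39 to 1841 at 24 hours, 468 to 2481 at 72 hours, 95 to 594 from 12 to 24 hours and 474 to 1224 from 24 to 72 hours. At 12 hours the count was 632 without control mouse A3250, 152 without A3259, 137 without A3280, 470 without A3258 and 288 without A3276. At 24 hours it was 1053 without A3250, 216 without A3259, 39 without A3280 and 139 without A3262. At 72 hours it was 714, 573 and 496 without these 3 controls, 468 without A3281, 567 without A3264 and 2481 without A3278, the mouse with the controls' code. From 12 to 24 hours it was 141 without A3258, 97 without A3276, 95 without A3277 and 214 without A3262, and from 24 to 72 hours 474 without A3262 and 726 without A3278. Genes shared by 12 and 24 hours numbered 4 to 193 and by 72 hours and 7 days 326 to 529, lowest without control mouse A3280. Lists past the test numbered 5 to 12 at 12 hours and 0 to 2 at 24 hours.

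List p over the same settings ran at 12 hours from 1.69e-05 to 0.302 for oxidative phosphorylation, 0.00535 to 0.452 for immediate early genes, 0.00132 to 0.324 for ribosomal proteins and 0.00101 to 0.108 for macrophage markers. The highest came without mouse A3258, but without A3252 for immediate early genes. Cardiac transcription factors at 24 hours ran from 0.0132 to 0.0809, highest without A3280. At 72 hours citric acid cycle ran from 0.0135 to 0.165, fasting from 0.00464 to 0.230, both highest without A3278, and cell cycle from 0.00115 to 0.229, highest without A3259. At 7 days glycolysis ran from 0.0287 to 0.0543 and proteasome from 0.00519 to 0.0637, both highest without A3283, and ribosomal proteins from 0.00104 to 0.0799, highest without A3345. Leaving out 1 mouse kept 1223 gene results on the same side of the threshold and lost 211, and kept 229 list results and lost 17.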

Other observations

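The test of GU-rich elements was chosen after the comparisons had been seen and before its own result.

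Further genes past the test at 72 hours were these. Thbs1, a secreted matrix protein of injured tissue, rose by 2.06 ± 0.26, the immediate early gene Egr3 by 1.76 ± 0.27, the glutathione gene Gclm by 1.15 ± 0.18 and the chaperone Dnajb9 by 1.10 ± 0.23. Hnrnph1, a splicing factor, rose by 0.93 ± 0.17, while the lectin gene Lgals4 (-1.37 ± 0.21) and the phosphatase gene Dusp18 (-1.61 ± 0.26) fell. Each of them stayed past the test when any 1 library was left out. With the column code as a term, a fit that rests on mouse A3278, Dnajb9 was at 0.50, Hnrnph1 at 0.69 and Gclm at 1.03. Thbs1 was at 2.48, Egr3 at 2.49, Lgals4 at -1.46 and Dusp18 at -1.65 in that fit. The list of NRF2 targets, which holds Gclm, had 3 of 16 genes higher and 2 lower at 72 hours (3 and 2 adjusted over the list alone), with a camera p of 0.908.

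At 7 days the p53 targets Trp53inp1 and Cdkn1a were at 1.79 ± 0.21 and 2.42 ± 0.30. Nmrk2, which makes a precursor of NAD in stressed muscle, rose by 4.98 ± 0.46 and Hmox1 by 4.13 ± 0.31. Among inflammatory genes Lcn2 rose by 4.94 ± 0.30, Saa3 by 4.50 ± 0.33 and Ccl2 by 4.27 ± 0.30, and the macrophage genes Ctss and Itgam rose by 4.89 ± 0.25 and 3.88 ± 0.19. Chil3 rose by 5.68 ± 0.18 but shares exon sequence with Chi3l4. The enzyme genes Pfkm (-2.43 ± 0.17) and Ldhb (-2.07 ± 0.20) and the light chain gene Myl2 (-2.85 ± 0.23) fell, while the sodium-calcium exchanger Slc8a1 rose by 1.21 ± 0.20. The clock genes Dbp (-3.56 ± 0.34), which overlaps Sphk2, and Hlf (-2.47 ± 0.25) fell, and Arntl rose by 1.88 ± 0.20.

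Celf1 binds GU-rich elements and can shorten the life of messenger RNA that carries them, so these transcripts were compared with others. Of 10362 genes with an annotated 3′ untranslated region of at least 50 bases and a known GC content, 379 carry TGTTTGTTTGT. Their median log2 fold change was -0.25 at 12 hours, -0.084 at 24 hours, -0.021 at 72 hours and 0.12 at 7 days. Medians of transcripts matched for length and GC content had 95% ranges from -0.30 to -0.22, -0.11 to -0.02, -0.07 to 0.03 and 0.01 to 0.19. The adjusted permutation p was 0.909 at each time, where the smallest possible unadjusted p is 0.0002. A general fall of transcripts with this element was thus not seen at the times when Celf1 was high, and at 7 days, with Celf1 at the control level, the test does not decide. Other forms of the element and binding itself were not tested.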
